A study of Bos grunniens with 9 samples.

How the data were processed

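Ribosome footprints were measured by ribosome profiling (sequencing of the mRNA stretches that ribosomes shield from RNase) in ovaries of 6-year-old yaks at 3 reproductive stages, with 3 biological replicates per stage and 9 libraries. Per the labels, ribosomal RNA was depleted with antisense probes and RNase H and the libraries were sequenced on an Illumina HiSeq X10. The submitters' processing notes credit Bowtie2 for alignment and RSEM for quantification; their versions and the genome build are not given in the sources used here. The labels do not say which animal each replicate came from, so the p-values measure the spread between these samples.

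The deposited tables hold estimated counts per gene and library, which the authors made with RSEM. They also hold FPKM values, which the authors derived from the counts by gene length and library size. The authors' comparison tables hold a log2 fold change per gene, the log2 ratio of the mean FPKM of 2 stages as recomputed from the values, and a p-value and an FDR for it, whose test is not stated in the deposited files. The analysis used the counts; the FPKM were not used here. Counts of one library did not differ between tables (0 values), and in a table of stage means with 38 complete genes, 114 of 114 means times 3 lay within 1.5 counts of the summed whole counts. The tables held 21652 genes, of which 3563 were at 0 in every library and 657 had no symbol. No RNA-seq of the same ovaries was matched, so footprint levels were not divided by mRNA levels, and mRNA amount and translation are not separated. Coordinates were not used here.

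Depth ran from 1.47 M to 28.94 M counts per library (M, 1e6). A level of 3 counts was taken as the floor, which is 0.104 CPM in the deepest library and 2.04 CPM in the shallowest. The 20 genes with most counts took 15.6 to 21.4% of a library. No library pair was close enough to be a duplicate (lowest chi-square per degree of freedom of a pair of libraries 15.4).

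Stages were compared in pairs and together with edgeR 4.0.16 in R 4.3.3 on all 9 libraries (filterByExpr, TMM factors from 0.876 to 1.144, quasi-likelihood F tests on a model of stage). Benjamini-Hochberg adjusted p under 0.05 counted as a call, in edgeR and in the other tools alike. Of the genes, 13936 passed the filter, with 99.9% of the counts, and the biological coefficient of variation was 34.5%. Standard errors of log2 fold changes come from this fit, and levels are TMM-normalised CPM with the SD of 3 libraries.

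Fixed lists, 34 in number with 942 entries, of which 922 matched a gene, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with a correlation estimated per list and with fry. At least 5 members had to pass the filter, which 33 lists met. A symbol carried by several identifiers was read at the identifier with most counts, and 323 KEGG pathways of 10 to 300 genes from the deposited annotation were tested in the same way. The score of a list in a library is the mean over its tested members of log2 CPM minus the gene's mean over the 9 libraries. The counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the members of 1 list. Each of the 33 lists was searched in each comparison without adjustment across lists, so some passes can arise by chance. In all, 12 members passed in estrus versus anestrus, 2 in pregnancy versus estrus and 9 in pregnancy versus anestrus. A gene in several lists counts once per list.

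Comparisons, lists, tests, thresholds and most alternatives were chosen before the data were examined. Genes were named by rule: 16 core ovarian genes whatever their result; the genes past the threshold with the highest and lowest log2 fold changes; and, as no gene passed, the 5 with the smallest unadjusted p. The last 2 parts took genes with a symbol, at 5 CPM or more in the higher stage, and with every library of one stage above every library of the other. Examples of lists were taken after their values were seen, up to 3 per called list by the smallest unadjusted p in the direction of the list, and genes that passed when adjusted over the list alone. Some results are left out of the text because the genes they need are withheld. Symbols such as IGHV4-39, pol and CYP21 rest on sequence similarity in the deposited annotation.

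Alternatives were DESeq2 1.42.0 (Wald tests, and a likelihood ratio test for the 3 stages), limma-voom with quality weights, the authors' deposited table, other scalings, other filters on low counts, a fit of the 6 compared libraries, a block for replicate number, and leaving out each library. Leaving out anestrus replicate 2 with pregnancy replicate 3, a robust prior, log2 library size as a covariate, nomenclature identifiers and summed identifiers were added after the data were examined.

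The procedure was tested on simulated data with 50 changed genes per fold and comparison and depths and spread taken from these libraries. It recovered 8 to 12% of 2-fold, 60 to 64% of 4-fold, 86 to 96% of 8-fold and 88 to 96% of 16-fold changes, and called 6 or 7 unchanged genes per comparison. Changed genes were drawn above a minimum total count, and all folds were changed together. Many changed genes ease the adjustment of p, so these shares may be too high for data with few changes or low counts. Each gene was given the same spread in every library, whereas limma-voom quality weights of the real libraries ran from 0.33 to 2. The shares may be too high for that reason too. A list of 40 genes changed by 0.5 on the log2 scale was called in each comparison and 0 of 30 unchanged lists were. Genes were simulated independently of each other, so this says nothing about false calls among lists whose members are correlated, as they are in these libraries (estimated correlations up to 0.73).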

Results

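Ribosome profiling sequences the stretches of mRNA that translating ribosomes shield from RNase, so the count of these footprints on a gene follows both the amount of its mRNA and how heavily that mRNA is translated. Footprints were counted in ovaries of 6-year-old yaks (Bos grunniens) at 3 reproductive stages, anestrus in April, estrus in August and pregnancy in December, with 3 biological replicates per stage and 9 libraries in all. Each stage was sampled in its own month, so differences between stages cannot be told apart from differences between seasons. Total counts (in M, 1 M being 1e6) were 15.4, 28.9 and 12 M in anestrus replicates 1 to 3, 6.11, 11.1 and 6.08 M in the estrus replicates, and 9.08, 4.97 and 1.47 M in the pregnancy replicates. The mean depth was 18.8 ± 8.96 M in anestrus, 7.75 ± 2.87 M in estrus and 5.17 ± 3.81 M in pregnancy (SD, n = 3 each), so stage and depth were not balanced. Every anestrus library was deeper than every library of the other stages. A floor of 3 counts equalled 0.104 CPM (counts per 1e6 counts) in the deepest library, anestrus replicate 2, and 2.04 CPM in the shallowest, pregnancy replicate 3.

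Libraries of one stage were not more alike than libraries of different stages. Pearson correlations of log2 CPM across genes, which are not independent replicates, ran from 0.875 to 0.954 within stages (median 0.927) and from 0.834 to 0.955 between stages (median 0.932). The first principal component, with 30.3% of the variance, set pregnancy replicate 3 apart from the other libraries, and the second, with 18.2%, set anestrus replicate 2 apart. These 2 libraries also carried the extreme scores of several gene groups. Granulosa and theca cell markers scored lowest in anestrus replicate 2 (-1.65 and -1.42, the mean over a list of each gene's log2 CPM minus its mean over the 9 libraries), where ribosomal protein genes and matrix remodelling enzymes scored highest (0.83 and 1.18). Cell cycle genes scored lowest in pregnancy replicate 3 (-1.46).

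Among 13936 genes tested with edgeR, 0 differed among the 3 stages at an adjusted p under 0.05, and 998 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.438). A likelihood ratio test in DESeq2 on the same counts called 56 genes, among them FABP6 (adjusted p = 2.67e-10) and CYP21 (adjusted p = 1.21e-07). Gene groups were fixed before the data were examined. By limma's camera with a preset correlation between genes, 12 of 33 lists passed in estrus versus anestrus, 6 in pregnancy versus estrus and 19 in pregnancy versus anestrus. With a correlation estimated for each list, 0 of these calls held in any comparison (smallest adjusted p = 0.734, 0.869 and 0.55), and fry called 0 lists (smallest adjusted p = 0.18, 0.539 and 0.364).

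**Figure D1:**
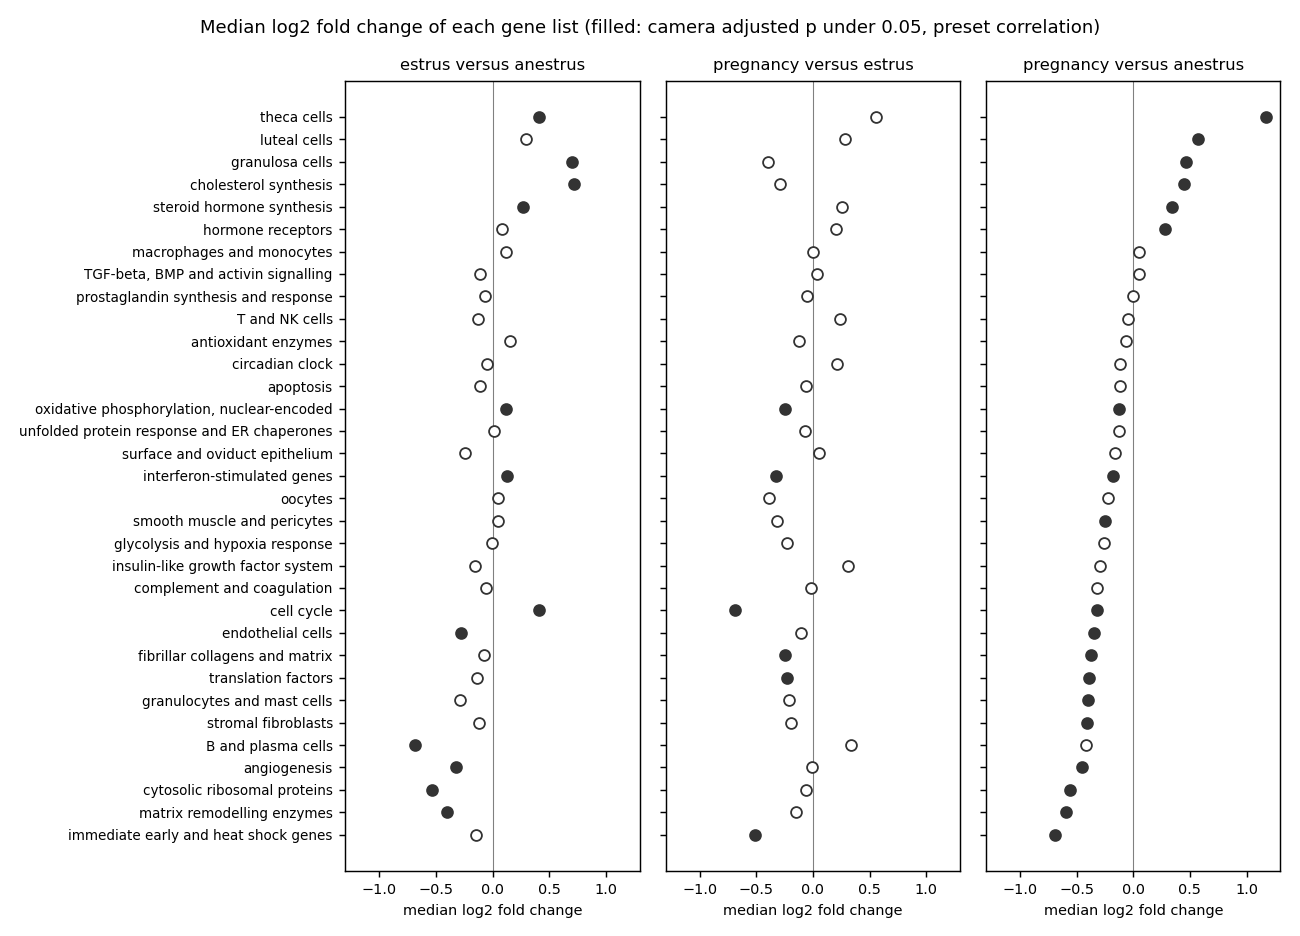
Median log2 fold change of the tested members of each of 33 gene lists (horizontal axis) in the 3 stage comparisons, 1 point per list, filled where camera with the preset correlation gave an adjusted p under 0.05. Cholesterol synthesis genes lie to the right in both comparisons with anestrus (0.72 and 0.45), ribosomal protein genes to the left (-0.54 and -0.56), and cell cycle genes at -0.69 in pregnancy versus estrus.

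The comparison of estrus with anestrus asked which footprint levels differed between the resting and the cycling ovary. By camera with the preset correlation, estrus ovaries carried more footprints on genes of cholesterol synthesis, the pathway that makes the precursor of steroid hormones, and fewer on genes of cytosolic ribosomal proteins. Both calls were lost with an estimated correlation (adjusted p = 0.734 for each). All 23 tested cholesterol synthesis genes had positive log2 fold changes, with a median of 0.72, and 76 of 77 ribosomal protein genes had negative ones, with a median of -0.54. As groups, markers of granulosa cells, which surround the oocyte and make estradiol, were higher by the same test (19 of 21 positive, median 0.70), as were cell cycle genes (33 of 38 positive, median 0.41), and markers of B and plasma cells, the antibody-forming lineage, were lower (8 of 10 negative, median -0.69). With an estimated correlation these 3 calls were lost too (adjusted p = 0.734, 0.864 and 0.734).

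By camera with the preset correlation, adjusted p was 2.83e-16 for the ribosomal list, 5.96e-11 for cholesterol synthesis, 9.75e-05 for granulosa cells, 4.11e-04 for the cell cycle and 1.72e-03 for B and plasma cells. Scores of cholesterol synthesis were 0.59 and 0.64 in estrus replicates 1 and 2, against -0.63 to -0.12 in anestrus, while estrus replicate 3 lay within the anestrus range at -0.38. Without anestrus replicate 2 the cholesterol median was 1.10 and the ribosomal median -0.26, and without estrus replicate 2 the cholesterol median was 0.44. The granulosa median was 1.42 without anestrus replicate 1 and 0.46 without anestrus replicate 2, and the group no longer passed without both anestrus replicate 2 and pregnancy replicate 3 (median 0.47). The cell cycle call was lost without estrus replicate 1 (median 0.20), and a fit with replicate number as a block gave a median of 0.27. Over all alternatives the cell cycle median ran from 0.20 to 1.00. The B cell call was lost without estrus replicate 3 (median -0.48). Its median was -1.08 without estrus replicate 1, -0.44 without pregnancy replicate 2 and -0.43 without pregnancy replicate 3. Pregnancy libraries enter this comparison only through the filter on low counts, the scaling factors and the shared estimate of spread.

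None of the single genes in these lists passed the test over all genes. The adjustment over the list alone, used here and below, was not extended across the 33 lists. Adjusted over the list alone, 9 cholesterol synthesis genes passed, among them MVK, which phosphorylates mevalonate (log2 fold change 1.16 ± 0.27 SE), FDFT1, which makes squalene (1.03 ± 0.28), and DHCR7, the last step to cholesterol (1.48 ± 0.44). Ribosomal examples were RPS13 (-0.78 ± 0.24), RPS10 (-0.75 ± 0.26) and RPS20 (-1.04 ± 0.36), and 0 of the 77 passed over the list alone, with 26 at an unadjusted p under 0.05. Of the granulosa markers, SLC35G1 had 1.63 ± 0.70, the BMP receptor BMPR1B 0.61 ± 0.29 and N-cadherin (CDH2) 1.38 ± 0.69. The cell cycle genes with the smallest unadjusted p were TK1 (0.70 ± 0.27), MCM5 (0.89 ± 0.37) and MCM2 (0.52 ± 0.25), which serve DNA synthesis. In the B cell list POU2AF1, a coactivator of immunoglobulin transcription, and MZB1, a chaperone of antibody secretion, passed when adjusted over the list alone. POU2AF1 stood at 3.0, 2.5 and 4.9 CPM in anestrus, at 0, 0.2 and 0 CPM in estrus and at 2.2, 1.0 and 2.4 CPM in pregnancy, while MZB1 had a log2 fold change of -1.99 ± 0.51. These examples, and those of the next comparisons, were chosen after their values were seen, among the 3 with the smallest unadjusted p in the direction of their list, or because they passed when adjusted over the list alone.

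Another 7 lists passed with adjusted p from 0.0158 to 0.0448. Medians were 0.13 for interferon-stimulated genes (21 of 29 positive), 0.27 for steroid hormone synthesis (18 of 24), 0.12 for nuclear-encoded oxidative phosphorylation (52 of 74) and 0.41 for theca cell markers (9 of 11). They were -0.28 for endothelial markers (18 of 21 negative), -0.40 for matrix remodelling enzymes (20 of 25) and -0.32 for angiogenesis genes (21 of 27). With an estimated correlation, these 7 lists had adjusted p from 0.734 to 0.881. Each call depended on single libraries, and some on other settings: without anestrus replicate 2 the endothelial, matrix, angiogenesis and theca calls were lost (medians -0.09, -0.15, -0.16 and 0.26), and without estrus replicate 2 the interferon, steroid and oxidative phosphorylation calls (0.14, 0.13 and -0.02). Anestrus replicates 1 and 3, estrus replicates 1 and 3 and pregnancy replicates 1 and 3 each decided at least 1 of the 7 calls as well. The pregnancy libraries did so only through the filter, the scaling and the shared spread, since their levels are not compared here. The theca call was also lost with upper quartile factors (0.43), library size alone (0.44), a replicate block (0.36) and nomenclature identifiers (0.41). With log2 library size in the model the theca (0.71), angiogenesis (-0.23), endothelial (-0.05) and matrix (0.08) calls were lost, with nomenclature identifiers that of oxidative phosphorylation (0.10) and with a stricter filter on low counts that of interferon-stimulated genes (0.13).

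The 4 genes given here are among the 5 with the smallest unadjusted p in estrus versus anestrus, of those at 5 CPM or more in the higher stage and without overlap between the libraries of the stages, and did not pass over all genes. IGHV4-39 (ENSBTAG00000048048), an immunoglobulin heavy chain variable segment, had 53.3 ± 19.2 CPM in anestrus and 14.1 ± 3.98 CPM in estrus (SD, n = 3 each), a log2 fold change of -1.92 ± 0.35 (SE, adjusted p = 0.704). OVGP1 (ENSBTAG00000005973), the oviduct-specific glycoprotein, had 49.9 ± 29.8 and 2.23 ± 2.66 CPM (-4.57 ± 0.96, adjusted p = 0.704), with log2 fold changes of -6.31 without estrus replicate 1 and -3.90 without estrus replicate 2, which had no count, and was the 1 gene of the surface and oviduct epithelium list that passed when adjusted over the list alone. A gene with the symbol pol (ENSBTAG00000052837) had 2.41 ± 1.08 and 9.98 ± 0.434 CPM (2.04 ± 0.44), and TNNT1 (ENSBTAG00000006419), the slow skeletal muscle troponin T, had 1.42 ± 0.308 and 6.90 ± 2.19 CPM (2.29 ± 0.49), both with adjusted p = 0.704.

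Over all genes edgeR called 0 genes in estrus versus anestrus, with 981 at an unadjusted p under 0.05 (405 higher in estrus and 576 lower) and a smallest adjusted p of 0.559. DESeq2 called 15 genes (7 higher, 8 lower) and the authors' deposited table lists 31 at its FDR under 0.05 (16 higher, 15 lower), with 13 shared. IGHV4-39, pol, TNNT1 and POU2AF1 were among the calls of both. Apart from TNNT1, the higher calls of both carried the symbols F52C9.6, pol or L1RE1. DESeq2 alone also called CYP21 higher in estrus (adjusted p = 0.00946). It stood at 2.3, 2.9 and 0.8 CPM in estrus and, near the floor, at 0.3, 0 and 0.2 CPM in anestrus. In the authors' deposited table CFDP2 and identifiers without a symbol were higher as well, so these counts do not describe known ovarian genes alone. The libraries of the stages did not overlap for 1622 genes (11.6%), where chance gives 10%. Without estrus replicate 3, edgeR called 2 genes, the histone gene H2BC3 (higher in estrus) and eef1as (lower), which were named after their values were seen.

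Of the 16 core ovarian genes, named whatever their result, 0 passed in edgeR in this comparison (smallest adjusted p = 0.708, for LHCGR, with an unadjusted value above 0.05). Log2 fold changes (± SE) on the path from cholesterol to estradiol were 0.10 ± 0.56 for STAR (ENSBTAG00000001608), 0.41 ± 0.47 for CYP11A1 (ENSBTAG00000006934), 0.43 ± 0.40 for HSD3B1 (ENSBTAG00000006769), 1.08 ± 1.04 for CYP17A1 (ENSBTAG00000014335) and -0.13 ± 1.23 for aromatase, CYP19A1 (ENSBTAG00000014890). The gonadotropin receptors had 1.61 ± 0.87 (FSHR, ENSBTAG00000032424) and 1.65 ± 0.75 (LHCGR, ENSBTAG00000016573). Among granulosa hormones and their regulator the values were 1.18 ± 0.77 for INHA (ENSBTAG00000009972), 0.54 ± 0.93 for INHBA (ENSBTAG00000048508), 1.35 ± 0.87 for AMH (ENSBTAG00000014955) and 0.08 ± 0.44 for FOXL2 (ENSBTAG00000031277). The steroid receptors had -0.14 ± 0.24 (PGR, ENSBTAG00000024648), 0.07 ± 0.46 (ESR1, ENSBTAG00000007159) and 0.93 ± 0.58 (ESR2, ENSBTAG00000004498), the prostaglandin F receptor PTGFR (ENSBTAG00000015902) -0.99 ± 0.49 and oxytocin, OXT (ENSBTAG00000008026), -2.33 ± 1.19. OXT had 3 counts or fewer in 2 estrus and 2 pregnancy libraries, so its values here and below rest on few counts. The signs for STAR, CYP19A1, INHBA, FOXL2 and ESR1 turned when single libraries were left out.

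In the annotated KEGG pathways, 77 of 323 passed camera with the preset correlation in estrus versus anestrus (8 higher, 69 lower) and 0 with an estimated one (smallest adjusted p = 0.433). The count was 24 without estrus replicate 2, 37 without estrus replicate 1, 39 without anestrus replicate 3 and 116 without estrus replicate 3.

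**Figure D2:**
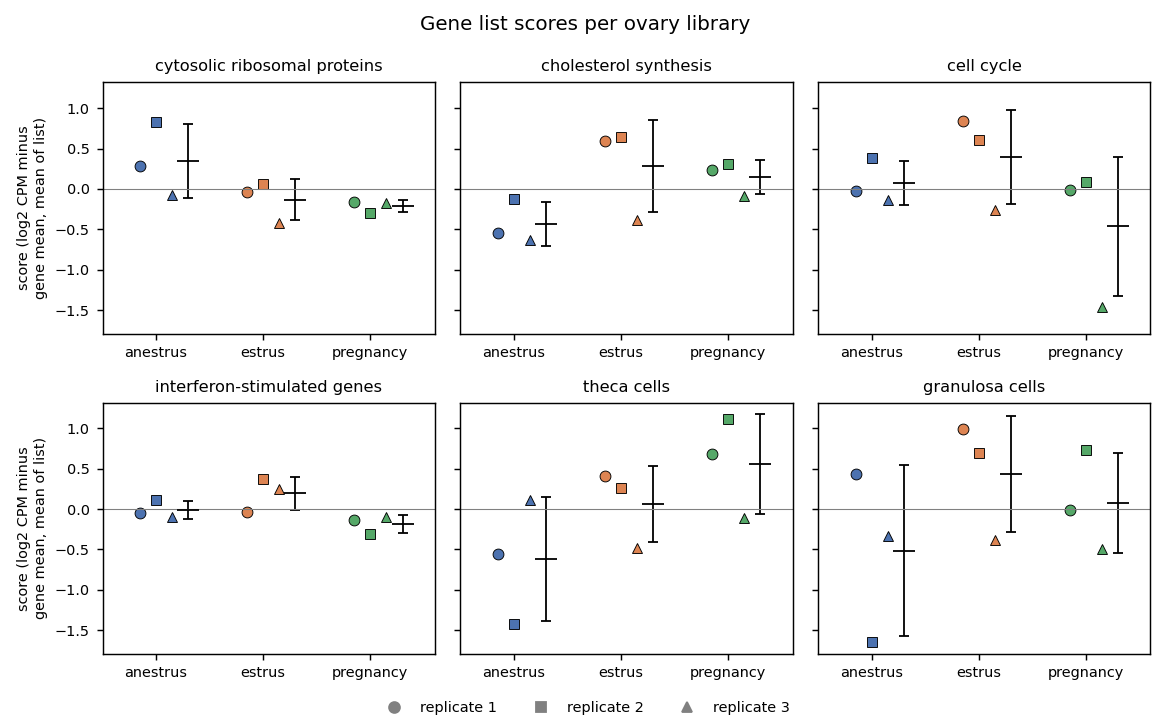
Scores of 6 gene lists in the 9 ovary libraries (vertical axis: mean over the list of log2 CPM minus the gene's mean over libraries), 1 symbol per library by replicate number, with the mean and SD of the 3 libraries of each stage as a bar. Anestrus replicate 2 is lowest for theca and granulosa markers (-1.42 and -1.65) and highest for ribosomal protein genes (0.83), and pregnancy replicate 3 is lowest for cell cycle genes (-1.46).

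The comparison of pregnancy with estrus asked what differed between the pregnant and the cycling ovary. By camera with the preset correlation, pregnant ovaries carried fewer footprints on cell cycle genes, with 37 of 38 members negative and a median log2 fold change of -0.69. Interferon-stimulated genes, which belong to the antiviral response, were also lower as a group (24 of 29 negative, median -0.33), and with an estimated correlation both calls were lost (adjusted p = 0.869 for each). Single genes with large differences included FGG, the gamma chain of the clotting protein fibrinogen, at 124 ± 92.3 CPM in pregnancy against 1.10 ± 1.24 CPM in estrus (SD, n = 3 each), though none passed over all genes.

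Camera with the preset correlation gave adjusted p = 1.52e-11 for the cell cycle and adjusted p = 3.58e-05 for interferon-stimulated genes. Cell cycle scores were 0.84 and 0.60 in estrus replicates 1 and 2 and -0.26 in estrus replicate 3, against -0.01, 0.08 and -1.46 in pregnancy replicates 1 to 3. Granulosa scores were alike in estrus (0.99, 0.70 and -0.38), and that list was not called here (15 of 21 negative, median -0.40, adjusted p = 0.306). Both calls held in every fit with the preset correlation, with the cell cycle median between -0.92 and -0.48 and the interferon median between -0.44 and -0.22. The cell cycle examples were thymidine kinase TK1 (log2 fold change -1.16 ± 0.28 SE), cyclin D2 (CCND2, -0.75 ± 0.23) and the replication clamp PCNA (-0.66 ± 0.21). For the interferon list they were MX1 (-0.98 ± 0.26), ISG15 (-1.20 ± 0.39) and IFIT1 (-0.80 ± 0.28). When adjusted over the list alone, 0 members of either list passed.

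Another 4 lists passed and were lower in pregnancy. Medians were -0.25 for nuclear-encoded oxidative phosphorylation (62 of 74 negative, adjusted p = 1.13e-04), with ATP5F1A at -0.63 ± 0.26, and -0.51 for immediate early and heat shock genes (24 of 26, adjusted p = 1.41e-03), with the transcription factor EGR2 at -2.18 ± 0.75 and the phosphatase DUSP1 at -1.28 ± 0.53. Translation factors had a median of -0.23 (34 of 40, adjusted p = 1.50e-03), with EIF5B at -0.82 ± 0.26, and collagens and other matrix proteins one of -0.25 (22 of 27, adjusted p = 4.49e-03), with fibrillin FBN1 at -0.87 ± 0.26. With an estimated correlation all 4 had adjusted p = 0.869. Without pregnancy replicate 3 the calls for oxidative phosphorylation (median -0.11), translation factors (-0.17) and collagens (-0.13) were lost, and without estrus replicate 2 as well (-0.11, -0.14 and -0.27). Of 19 alternatives, the estimated correlation and fry included, 6, 6 and 7 ended these calls in that order. The medians nearest 0 were -0.10, -0.07 and -0.10. The immediate early call was lost without estrus replicate 3 (-0.15) or pregnancy replicate 1 (-0.51), and the collagen call also without estrus replicate 3 (-0.31). Immediate early genes scored -0.49, 0.10 and 0.96 in estrus replicates 1 to 3. They rose with replicate number in the other stages too (-0.51, 0.27 and 0.81 in anestrus, -0.73, -0.58 and 0.15 in pregnancy). Levels of this list thus followed replicate number as well, for a reason that was not tested.

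The 5 genes named by the smallest unadjusted p each had adjusted p = 0.522. SHISA2 (ENSBTAG00000018214), which modulates Wnt and FGF signalling, had 1.15 ± 0.447 CPM in estrus and 6.70 ± 1.09 CPM in pregnancy (SD, n = 3 each), a log2 fold change of 2.51 ± 0.43 SE. PLBD1 (ENSBTAG00000015562), a phospholipase B-like protein, had 21.4 ± 3.71 and 5.04 ± 3.04 CPM (-2.04 ± 0.36). FGG (ENSBTAG00000006745) had 21.9, 150 and 201 CPM in the pregnancy libraries and at most 5.22 CPM in any other, with no fold given since 2 estrus libraries were at the floor of 3 counts. The palmitoyltransferase ZDHHC2 (ENSBTAG00000044194) had 19.6 ± 5.61 and 51.4 ± 2.68 CPM (1.39 ± 0.26), and the receptor kinase GRK2 (ENSBTAG00000005832) had 22.3 ± 2.79 and 45.2 ± 2.73 CPM (1.02 ± 0.20).

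In edgeR 0 genes passed in pregnancy versus estrus, with 1035 at an unadjusted p under 0.05 (590 higher in pregnancy and 445 lower, or 809 and 262 when scaled by library size alone). DESeq2 called 29 genes (20 higher, 9 lower) and the authors' deposited table lists 23 at its FDR under 0.05 (13 higher, 10 lower), with 15 shared. SHISA2, PLBD1, FGG and ZDHHC2 were called by both and GRK2 by DESeq2 alone. The DESeq2 call with the smallest adjusted p, L1RE1 (ENSBTAG00000050903), rested on 1 library. It stood at 33.8, 0 and 0 CPM in estrus replicates 1 to 3 and at 0 CPM in pregnancy. DESeq2 called it in pregnancy versus anestrus too (3.0, 0 and 5.6 CPM in anestrus). The libraries of the stages did not overlap for 1900 genes (13.6%, chance 10%).

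Of the core genes 0 passed in pregnancy versus estrus in edgeR. HSD3B1, which makes progesterone, had the smallest unadjusted value, with a log2 fold change of 1.38 ± 0.41 (adjusted p = 0.656), beside 1.29 ± 0.58 for STAR, 0.76 ± 0.48 for CYP11A1, 0.91 ± 1.04 for CYP17A1 and -1.42 ± 1.29 for CYP19A1. The progesterone receptor PGR had -0.73 ± 0.24 (adjusted p = 0.656). The others were -0.17 ± 0.86 for FSHR, 0.18 ± 0.74 for LHCGR, -0.40 ± 0.76 for INHA, -1.54 ± 0.95 for INHBA, 0.34 ± 0.85 for AMH and 0.06 ± 0.44 for FOXL2. ESR1 had -0.03 ± 0.47, ESR2 -0.50 ± 0.60, PTGFR 1.06 ± 0.50 and OXT -0.36 ± 1.35. A second identifier with the symbol STAR, which held 43.6% of that symbol's counts, is listed at 1.84 (FDR 0.00949) in the authors' deposited table. The signs for FSHR, LHCGR, INHA, AMH, FOXL2, ESR1 and OXT turned when single libraries were left out.

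By the same camera test 25 KEGG pathways passed in pregnancy versus estrus (9 higher, 16 lower) and 0 with an estimated correlation (smallest adjusted p = 0.784). Without pregnancy replicate 3 the balance turned to 16 higher and 6 lower. The count was 7 without estrus replicate 1 or 2, 16 without pregnancy replicate 1 and 62 without estrus replicate 3.

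Pregnancy was also compared with anestrus. By camera with the preset correlation, markers of theca cells, the androgen-making layer of the follicle, were higher as a group in pregnancy (10 of 11 positive, median log2 fold change 1.17), a call lost with an estimated correlation (adjusted p = 0.55). Genes of cholesterol synthesis (22 of 23 positive, median 0.45), steroid hormone synthesis (17 of 24, median 0.34) and luteal cells, which make progesterone (14 of 19, median 0.57), were also higher by that test, and their calls were lost likewise (adjusted p = 0.55 for each). All 77 ribosomal protein genes had negative log2 fold changes, with a median of -0.56, again with an adjusted p of 0.55 at an estimated correlation. Among single genes CYP21, steroid 21-hydroxylase, stood at 8.26 ± 3.98 CPM in pregnancy and 0.142 ± 0.133 CPM in anestrus (SD, n = 3 each), without passing over all genes.

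Camera with the preset correlation gave adjusted p = 9.59e-21 for the ribosomal list, 3.00e-07 for cholesterol synthesis, 6.68e-05 for theca cells, 6.35e-04 for steroid hormone synthesis and 0.02 for luteal cells. Theca scores were -0.55, -1.42 and 0.11 in anestrus replicates 1 to 3 and 0.68, 1.11 and -0.11 in the pregnancy replicates. The theca, luteal and steroid lists share STAR, CYP11A1 and HSD3B1, so they are not independent of each other. The theca list also shares LHCGR with the luteal list and CYP17A1 with the steroid list. The luteal and steroid lists share SCARB1 and FDX1 besides. The theca call held in every fit with the preset correlation, with medians from 0.89 to 1.72. Without anestrus replicate 2, the ribosomal median was -0.31 and the cholesterol median 0.72. The steroid list passed with a median of only 0.08 without pregnancy replicate 2, of 0.58 without anestrus replicate 1 and of 0.59 without pregnancy replicate 3. The luteal call was lost without anestrus replicate 1, pregnancy replicate 1 or pregnancy replicate 2 (medians 0.59, 0.54 and 0.31). Over all alternatives the cholesterol median ran from 0.34 to 1.07, the steroid median from 0.08 to 0.86 and the luteal median from 0.31 to 1.37.

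HSD3B1 passed in the theca, luteal and steroid lists when adjusted over the list alone, at 52.8 ± 19.0 CPM in anestrus and 184 ± 89.9 CPM in pregnancy (SD, n = 3 each), a log2 fold change of 1.81 ± 0.42 SE. Beside it stood CYP11A1, which cleaves the cholesterol side chain (1.17 ± 0.48), and STAR, which carries cholesterol into mitochondria (1.39 ± 0.57). HSD3B1, CYP11A1 and STAR are in the theca and luteal lists alike, so they do not tell these cell types apart. In the luteal list the prolactin receptor PRLR (2.79 ± 0.73), PGR (-0.87 ± 0.24) and the prostaglandin E synthase PTGES (-2.26 ± 0.71) passed as well, and PRLR and PGR also in the list of hormone receptors. Members of the cholesterol list were SREBF2, its master transcription factor (0.61 ± 0.18), TM7SF2 (1.87 ± 0.56) and SCAP (0.98 ± 0.36), with 0 past the test over the list alone. RPS4X (-0.81 ± 0.24), RPS13 (-0.80 ± 0.25) and RPL12 (-1.10 ± 0.35) were examples of the ribosomal list, again with 0 past the test over the list alone. IGF1, a growth factor of the insulin-like family, passed over its own list (-1.87 ± 0.41).

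Of the other lists, 2 were higher and 12 lower in pregnancy than in anestrus. Granulosa markers (17 of 21 positive, median 0.47, adjusted p = 0.0153) and hormone receptors (15 of 20, median 0.28, adjusted p = 0.0372) were the higher ones. Translation factors (36 of 40 negative, median -0.39, adjusted p = 5.53e-07), collagens and other matrix proteins (23 of 27, -0.37, adjusted p = 6.21e-05), matrix remodelling enzymes (20 of 25, -0.59, adjusted p = 9.57e-05) and cell cycle genes (33 of 38, -0.32, adjusted p = 1.69e-04) were lower. EEF1A1, the main elongation factor, had -0.93 ± 0.29, collagen VI chain COL6A3 -1.47 ± 0.41, the metalloproteinase MMP19 -1.06 ± 0.30 and PCNA -0.50 ± 0.21. Endothelial markers (19 of 21, -0.35, with the VEGF receptor FLT1 at -1.14 ± 0.47), angiogenesis genes (20 of 27, -0.45, with EPAS1 at -1.15 ± 0.30) and immediate early genes (21 of 26, -0.69, with DUSP1 at -1.66 ± 0.54) were also lower, with adjusted p from 1.03e-03 to 8.40e-03. Stromal fibroblast (16 of 22, -0.41), interferon-stimulated (20 of 29, -0.18), smooth muscle (15 of 20, -0.25), granulocyte (8 of 9, -0.40) and oxidative phosphorylation genes (49 of 74, -0.13) passed with adjusted p from 0.0458 to 0.0490. With an estimated correlation these 14 lists had adjusted p from 0.55 to 0.91.

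Single libraries decided most of these 14 calls. Without anestrus replicate 2, the calls of granulosa markers (median 0.12), hormone receptors (0.22), endothelial markers (-0.17), angiogenesis (-0.15), interferon-stimulated genes (-0.15), granulocytes (-0.43) and oxidative phosphorylation (-0.02) were lost, and medians shrank to -0.16 for translation factors and -0.28 for matrix remodelling enzymes. Without pregnancy replicate 3, the calls of the cell cycle (-0.09), angiogenesis (-0.41), hormone receptors (0.25), granulocytes (-0.39) and oxidative phosphorylation (0.02) were lost. Immediate early genes were at 0.09 without anestrus replicate 3 and no longer passed, nor did they without pregnancy replicate 1 (-0.72). Stromal fibroblast and smooth muscle calls were lost without anestrus replicates 1 (-0.28 and -0.20) or 3 (-0.39 and -0.19) and without pregnancy replicates 1 (-0.42 and -0.28) or 2 (-0.43 and -0.30). Granulosa markers turned to -0.05 without pregnancy replicate 2. With log2 library size in the model, the medians turned to 0.47 for the cell cycle, 0.33 for oxidative phosphorylation, 0.14 for matrix remodelling enzymes, 0.08 for collagens, 0.06 for endothelial markers and 0.01 for translation factors. In that fit the cell cycle (adjusted p = 5e-04) and oxidative phosphorylation (adjusted p = 1.08e-05) passed as higher in pregnancy, where adjusted p over the alternatives of these lists ran from 6e-07 to 0.737 and from 1.08e-05 to 0.91. The same fit ended the calls of angiogenesis (-0.02), hormone receptors (0.09), interferon-stimulated genes (-0.02), granulosa markers (0.79), stromal fibroblasts (-0.27) and granulocytes (-0.16). Of 19 alternatives, the estimated correlation and fry included, 9 ended the granulocyte call. The calls of hormone receptors, interferon-stimulated genes, smooth muscle and stromal fibroblasts were each ended by 8, not all of which are named here.

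Of the 5 genes with the smallest unadjusted p, the 4 given here did not pass. FABP6 (ENSBTAG00000010632), a bile acid binding protein of the ileum, stood at 0.0968 ± 0.0848 CPM in anestrus, a mean under the floor of each anestrus library, and at 7.83 ± 4.07 CPM in pregnancy (SD, n = 3 each). CYP21 (ENSBTAG00000001443), with the levels given above, was also near the floor in anestrus, so no fold is given for either. TPPP3 (ENSBTAG00000019822), a tubulin-binding protein, had 20.7 ± 0.474 CPM in anestrus and 6.18 ± 0.774 CPM in pregnancy (log2 fold change -1.72 ± 0.25 SE), with estrus between them at 13.1 ± 2.96 CPM. These 3 had adjusted p = 0.236. FGG (5.77 ± 1.10) had adjusted p = 0.718.

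**Figure D3:**
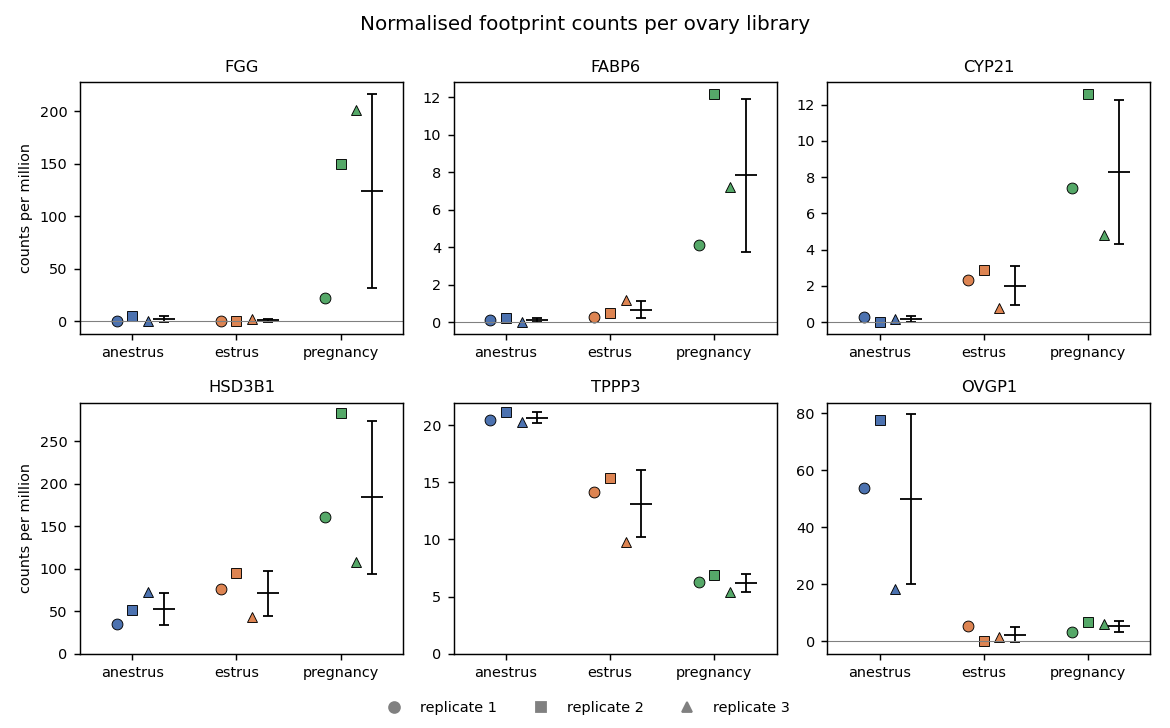
Normalised footprint counts (CPM, vertical axes from 0) of 6 genes in the 9 ovary libraries, 1 symbol per library by replicate number (circle, square and triangle for 1 to 3), with the mean and SD of the 3 libraries of each stage as a bar. All 3 pregnancy libraries lie above every other library for FGG, FABP6, CYP21 and HSD3B1 and below every other library for TPPP3, and all 3 anestrus libraries lie above every other library for OVGP1, though none of the 6 passed edgeR over all genes. All but HSD3B1 were named by a rule that asks for no overlap between the compared stages, which fixed part of this separation.

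In pregnancy versus anestrus edgeR called 0 genes, with 951 at an unadjusted p under 0.05 (446 higher in pregnancy and 505 lower, a balance that turned to 634 and 279 when scaled by library size alone). DESeq2 called 28 (13 higher, 15 lower) and the authors' deposited table lists 36 at its FDR under 0.05 (18 higher, 18 lower), with 24 shared. FABP6, TPPP3, CYP21, FGG, HSD3B1 and PRLR were called by both, and TM7SF2, DUSP1 and OVGP1 only in the authors' deposited table. The libraries of the stages did not overlap for 1782 genes (12.8%, chance 10%).

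The remaining core genes did not pass in edgeR either. CYP17A1 had a log2 fold change of 1.99 ± 1.07, with 411 ± 457 CPM in anestrus and 1634 ± 1180 CPM in pregnancy (SD, n = 3 each), and CYP19A1 had -1.56 ± 1.29. Receptors of the gonadotropins had 1.43 ± 0.88 (FSHR) and 1.83 ± 0.76 (LHCGR). Values were 0.78 ± 0.76 for INHA, -1.0 ± 0.94 for INHBA, 1.69 ± 0.87 for AMH and 0.14 ± 0.44 for FOXL2. They were 0.04 ± 0.47 for ESR1, 0.43 ± 0.60 for ESR2, 0.08 ± 0.49 for PTGFR and -2.69 ± 1.31 for OXT. Adjusted p ran from 0.718 to 0.983 over the 16 genes, and the signs for CYP19A1, INHA, INHBA, FOXL2, ESR1 and PTGFR turned when single libraries were left out.

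In the KEGG pathways 20 passed in pregnancy versus anestrus (1 higher, 19 lower) and 0 with an estimated correlation (smallest adjusted p = 0.833). The count was 12 without anestrus replicate 3, 10 without pregnancy replicate 2 and 52 without pregnancy replicate 3, of which 15 were higher and 37 lower.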

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

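The fits without anestrus replicate 2 and pregnancy replicate 3 together, with log2 library size as a covariate, with a robust prior, with nomenclature identifiers and with summed identifiers were tests chosen only after the results were seen. Of 3741 alternative values for 163 gene results, 3634 kept direction and side of the threshold, 35 passed it and 72 reversed, and of 702 values for 37 list results 506 kept both, 183 lost the call and 13 reversed. No gene passed in the main fit, so gene values had no call to lose. Their share that kept its side is therefore no measure of how firm a call is. The pseudocount alternative for normalised values was not run, since counts were used. Depth is partly confounded with stage (anestrus deepest on average), and 3 counts are 2.04 CPM in pregnancy replicate 3. Scaling by library size alone moved the median of all genes by 0.03, 0.10 and 0.13 in estrus versus anestrus, pregnancy versus estrus and pregnancy versus anestrus. Residuals of libraries with the same replicate number correlated at -0.03 to 0.26 and 7 of 9 libraries correlated best with their own number. Most cross-stage partners of a library carried another number, so an effect of replicate number was not excluded. With a replicate block edgeR called 0 genes and camera 11, 6 and 17 lists and 69, 24 and 22 pathways in that order. The block ended the calls of theca cells in estrus versus anestrus (0.36) and of hormone receptors (0.27) and granulocytes (-0.39) in pregnancy versus anestrus. For the changes below the cause was not tested, except that fewer libraries were fitted where some were left out.

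In the same order, edgeR called 0 genes (981, 1035 and 951 at an unadjusted p under 0.05), DESeq2 15, 29 and 28, and the authors' deposited table listed 31, 23 and 36, with 56 genes differing among the stages in DESeq2. Leaving out 1 library gave 0 to 2 genes in estrus versus anestrus, 0 to 1 in pregnancy versus estrus, 0 in pregnancy versus anestrus and 0 to 1 among the stages. Lists called were 12, 6 and 19 with the preset correlation, 0, 0 and 0 with a correlation estimated per list and 0, 0 and 0 with fry; leaving out 1 library gave 7 to 14, 4 to 10 and 13 to 20. In pregnancy versus anestrus 12 lists were called with the covariate and 10 without the 2 libraries. Pathways called were 77, 25 and 20, and 0, 0 and 0 with a correlation estimated per pathway; leaving out 1 library gave 24 to 116, 7 to 62 and 10 to 52, and leaving out the 2 libraries 16 in pregnancy versus estrus and 36 in pregnancy versus anestrus.

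Reversals with the covariate were, in estrus versus anestrus, matrix remodelling enzymes 0.08, INHBA 0.00, ESR1 -0.52 and OXT 0.00, in pregnancy versus estrus OXT 1.26, and in pregnancy versus anestrus collagens 0.08, matrix remodelling enzymes 0.14, cell cycle 0.47, translation factors 0.01, oxidative phosphorylation 0.33, endothelial cells 0.06, ESR1 -1.23, ESR2 -0.43, PTGFR -1.71, OXT 1.27, AMHR2 -0.36, NDUFS5 0.01, NDUFA2 0.01, FOSL1 1.04 and MX1 0.02. Without the 2 libraries they were FOXL2 -0.23 and ESR1 -0.09 in estrus versus anestrus, FSHR 0.13 in pregnancy versus estrus, and cell cycle 0.10, oxidative phosphorylation 0.11, ESR1 -0.68, ESR2 -0.20 and PTGFR -0.98 in pregnancy versus anestrus. With limma-voom and quality weights they were CYP19A1 1.73 and ESR1 -0.27 (estrus versus anestrus), FOXL2 -0.01 (pregnancy versus estrus), and CYP19A1 0.31, ESR1 -0.61 and PTGFR -0.86 (pregnancy versus anestrus). A replicate block gave CYP19A1 1.17 in estrus versus anestrus and CYP19A1 0.07, INHBA 0.07 and PTGFR 0.00 in pregnancy versus anestrus. Scaling by library size alone gave ESR1 0.12 and the authors' deposited table ESR1 0.15 and OXT 0.01 in pregnancy versus estrus, and summed identifiers STAR -0.06 in estrus versus anestrus.

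Leaving out 1 library turned these signs (lowest to highest). In estrus versus anestrus they were oxidative phosphorylation -0.02 to 0.30, STAR -0.48 to 1.09, CYP19A1 -0.73 to 3.56, INHBA -0.47 to 2.55, FOXL2 -0.27 to 0.31 and ESR1 -0.17 to 0.59. In pregnancy versus estrus they were FSHR -0.81 to 0.34, LHCGR -0.27 to 0.57, INHA -1.18 to 0.31, AMH -0.48 to 0.79, FOXL2 -0.38 to 0.40, ESR1 -0.60 to 0.32 and OXT -1.56 to 1.94. In pregnancy versus anestrus they were oxidative phosphorylation -0.25 to 0.02, immediate early genes -1.12 to 0.09, granulosa cells -0.05 to 0.97, CYP19A1 -2.15 to 2.13, INHA -0.02 to 1.94, INHBA -1.55 to 1.01, FOXL2 -0.31 to 0.45, ESR1 -0.52 to 0.56 and PTGFR -0.74 to 0.48.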

Other observations

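The splits for genes, the test of anestrus replicate 2 alone, both tests of FGG and the single-library test of OVGP1 were tests chosen only after the results were seen.

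Each stage pair has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. For genes in edgeR, the real split and the highest other gave 0 and 1 (estrus versus anestrus), 0 and 1 (pregnancy versus estrus) and 0 and 0 (pregnancy versus anestrus), with 10, 10 and 10 of 10 splits giving as many, which a real count of 0 makes certain. At an unadjusted p under 0.05 the real counts were 981, 1035 and 951, against 1267, 1443 and 890 for the highest other split. For lists the values were 12 and 17, 6 and 12, and 19 and 17, with 5, 7 and 1 of 10 splits giving as many. For pathways they were 77 and 68, 25 and 61, and 20 and 39, with 1, 3 and 6 of 10. Among the 3 stages all 100 splits drawn of 280 gave as many genes as the real 0 (highest other 2), which is certain too. At an unadjusted p under 0.05 the real count was 998 and the highest other 1554, and 13 of the 100 gave as many, so chance was not excluded.

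Ribosomal protein genes were lower in pregnancy than in anestrus, with a median log2 fold change of -0.56 over 77 members (quartiles -0.71 and -0.48) by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.55) and with fry (adjusted p = 0.393). Without anestrus replicate 2 the median was -0.31 (quartiles -0.41 and -0.21) with 75 members negative, so the shift shrank but was not gone. Members are correlated (estimated correlation 0.73), so their number is not independent support. Scores were 0.28, 0.83 and -0.08 in anestrus replicates 1 to 3 and -0.16, -0.30 and -0.17 in the pregnancy replicates. Anestrus replicate 3 lay near the pregnancy libraries, so few libraries carry the remaining shift. Library depth stays open, since every anestrus library was deeper than every pregnancy library. With log2 library size as a covariate the median was -0.25 (quartiles -0.37 and -0.06), under 0.5 of its former size, with 67 members negative. A biological difference between the stages may also underlie it and was not tested apart from depth.

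FGG stood at 21.9, 150 and 201 CPM in the pregnancy libraries. Liver tissue or liver RNA in the pregnancy samples is argued against, since liver makes all 3 fibrinogen chains and FGA plus FGB reached at most 2.91% of FGG in any pregnancy library. FGA was at 0 CPM in every library, so its row may be unable to show liver RNA, and the sum rests on FGB (6, 0 and 2 counts in pregnancy). Albumin (ALB) was at most at 1.18 CPM in any library. The lowest pregnancy library was 4.19 times the highest of the other stages, but FGG was named by a rule that asks for stages without overlap, so this ratio does not weigh on a single pregnancy library. Expression by ovarian cells in pregnancy is a hypothesis that may explain the values and was not tested.

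OVGP1 stood at 53.8, 77.7 and 18.4 CPM in the anestrus libraries. The lowest was 2.74 times the highest library of the other stages, which does not weigh on a single anestrus library either, since the same rule named OVGP1. Oviduct epithelium in the anestrus samples stays open as a candidate source: 23 tested genes of motile cilia, which that epithelium carries, had a median log2 fold change of -0.65 in estrus over anestrus (quartiles -1.07 and 0.44), 15 negative and 8 positive. Of 8 markers, 6 had lower means in estrus and 2, KRT8 and MUC16, higher means. For KRT8 and MUC16, and also for PAX8 and EPCAM among the lower ones, the difference was smaller than the larger SD. Levels were as follows (CPM in anestrus and estrus, SD, n = 3 each): TEKT1 2.37 ± 0.611 and 0.117 ± 0.103, FOXJ1 2.16 ± 1.48 and 0, CAPS 4.73 ± 3.8 and 0.381 ± 0.346, TPPP3 20.7 ± 0.474 and 13.1 ± 2.96, PAX8 3.11 ± 2.76 and 2.47 ± 1.5, EPCAM 6.85 ± 5.4 and 2.73 ± 1.13, KRT8 107 ± 21 and 163 ± 103, MUC16 0.608 ± 0.532 and 0.872 ± 1.05. The summed cilia list stood at 149, 105 and 91.2 against 133, 95.5 and 100 CPM, a sum carried in large part by MNS1 (52.09, 20.43 and 40.63 against 72.65, 44.14 and 38.28 CPM), and the surface and oviduct epithelium list was not called (adjusted p = 0.663). Like OVGP1, FOXJ1 (2.45, 3.48 and 0.564 CPM in anestrus replicates 1 to 3), CAPS (8.01, 5.61 and 0.564) and EPCAM (10.9, 8.89 and 0.726) were lowest in anestrus replicate 3. KRT8 (120, 82.6 and 118) was not. FOXJ1 was lower in estrus in the authors' deposited table (FDR 0.0267), and TEKT1 was called by the DESeq2 likelihood ratio test (adjusted p = 0.038). A difference between ovaries of the stages may also underlie the OVGP1 levels and was not tested apart from oviduct epithelium.

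Other values were picked after they were seen. DESeq2 gave lower counts in estrus than in anestrus for the immunoglobulin light chain segments IGLV2-14 at 2 identifiers (adjusted p = 0.00946 and 0.0213) and the heavy chain segment IGHV4-39 (adjusted p = 0.00224). In pregnancy versus anestrus it called LCN2, an iron-binding defence protein (log2 fold change 2.96, adjusted p = 0.00206), C4BPA, a complement inhibitor (2.42, adjusted p = 0.00709), and VTCN1, an inhibitor of T cells near the floor in anestrus (adjusted p = 0.000759). In edgeR over all genes 0 genes passed in these comparisons.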
